A study of Sus scrofa with 8 samples.

How the data were processed

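Liver RNA of 8 pigs was measured, 4 Korean native pigs (KNP, 7 months old) and 4 Yorkshire pigs (YS, 6 months old), with 1 array per animal. According to the labels, total RNA was extracted with Trizol from the tip of the largest liver lobe, labelled with biotin and hybridized to the Affymetrix porcine array, and the pigs were kept under the same conditions. The submitters' processing notes name GCOS 1.3. The deposited values are an intensity per probe set on a linear scale. The mean of the values between the percentiles 2 and 98 was 500.1 on each of the 8 arrays, so the authors' values carry a scaling per array, and no further normalization between arrays was visible in them. The signal algorithm and the background step are not given in the sources used here, and the table holds no detection calls. For arrays there is no count of reads; the number of arrays, 4 per breed, limits the precision of each value.

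Of 24123 probe sets, 124 controls were left out of the comparison and used only to describe the arrays, which left 23999. The intensity was transformed as log2(value + 16). The medians of the arrays on this scale differed by 0.22, under the limit of 0.5 above which quantile normalization would have been used, so no further scaling was applied. The lower 40% of probe sets by mean over the 8 arrays were left out, and 14399 were tested. The array annotation lists 10297 probe sets with a symbol, 10099 of them with 1 and 198 with several. Of the former, 9989 were found in the gene table of the pig genome (Sscrofa11.1), and all 9989 had the same symbol there. Among the probe sets tested, 7189 carried 1 symbol, 154 several and 7056 none. Probe sets with several symbols or none were counted and not named. A gene with several probe sets (5423 genes in all) was represented by the one with the highest mean, and for named genes the others are given where one has the opposite sign; members of a list are counted by this probe set alone.

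The comparison of KNP with YS was fitted per probe set with limma (lmFit and eBayes with an intensity trend), with a two-sided moderated test, breed as the only term and Benjamini-Hochberg adjustment over the 14399 probe sets. The threshold was an adjusted p under 0.05. Differences are KNP minus YS on the log2 scale with their standard error (SE), and means per breed are intensities with the SD over 4 animals. Age is tied to breed and cannot enter as a term, and dates of hybridization are not given in the sources used here. The replicate numbers name different animals in the 2 breeds, so the animals were not paired.

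Gene lists were tested with camera from limma, at a preset correlation between genes of 0.01, on 1 probe set per gene. Of 39 lists written from textbook knowledge (26 pathways and 13 cell types), 33 had at least 5 tested members (25 pathways and 8 cell types), and their p-values were adjusted together. The test was repeated with a correlation estimated from the data and with fry. The members of each list that passed were counted over all probe sets tested and again adjusted over the list alone. The share of the total sum of squares that lay between the breeds was tested with an exact permutation test over the 35 splits of 8 arrays into 4 and 4. Measures with 1 value per array were compared with two-sided exact permutation tests, whose smallest possible p at this size is 0.0286.

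The genes named are the 12 with the largest rise and the 12 with the largest fall among genes past the threshold whose 4 KNP values lay all above or all below the 4 YS values. From each list past the threshold up to 4 members with the smallest p and up to 6 members past the threshold are named, and from other lists 1 or 2 members. FASN, ACACA, SCD, ME1, IGF1, IGFBP1, IGFBP2, GHR, CYP2E1, SULT2A1 and CYP2A19 are always given; IGFBP3 was not among the probe sets tested. The groups, the test, the lists, this rule and the alternatives were chosen before the data were examined, except for a pair of alternatives chosen after seeing the data, cyclic loess normalization and the ratio of the actin 3' to 5' control signals as a covariate. The alternatives chosen in advance were a pseudocount of 1 or 64, quantile normalization, median centring, no filter, the lower 60% left out, no intensity trend, array weights, a replicate block, each animal left out in turn, a minimum change of 2-fold, a threshold of 0.01, and the mean of all probe sets of a gene.

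To set list medians beside brightness, each of 15 lists was compared with 10000 random lists of genes outside it, each member replaced by 1 of the 50 such genes nearest to it in mean intensity. For the 10 lists called lower, the mean of the list minus the mean of these genes was also compared between the breeds per array, by an exact permutation test. The fit was tested on simulated data: of 50 probe sets changed at each size, it recovered 6% at 1.5-fold, 44% at 2-fold, 80% at 4-fold and 100% at 8-fold, with 5 other calls among 14399 probe sets. A list shifted by 1 on the log2 scale was called with an adjusted p of 2.5e-10, and 0 other lists were called. The simulated noise was drawn independently for each probe set, without correlation between genes. It therefore does not show how often lists are falsely called on real arrays. The tools were R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9.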

Results

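Liver transcripts of 8 pigs were measured on the Affymetrix porcine array, in 4 animals of an indigenous Korean breed, the Korean native pig (KNP), and 4 animals of the commercial Yorkshire breed (YS). The KNP animals were 7 months old and the YS animals 6 months, so each difference is one of breed and age together, and of any hybridization batch that followed breed, since dates are not given in the sources used here. The median intensity of the arrays ran from 152 to 179, and the highest intensity from 50730 to 60066 on KNP arrays and from 83646 to 95919 on YS arrays. The number of arrays limits the precision of every value. The comparison asks which genes are expressed at different levels in the livers of the breeds.

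SDS, which turns serine into pyruvate and so feeds amino acids into glucose production, rose in KNP, at an intensity of 1922 ± 1317 against 127 ± 115 in YS (SD, n = 4 per breed; log2 difference 4.07, SE 0.70, adjusted p = 0.0336). ATP2A2, the calcium pump of the endoplasmic reticulum, rose by 1.74 with its brightest probe set (SE 0.21, adjusted p = 0.0102, 4878 ± 789 against 1485 ± 488). Its other probe sets showed 0.062, −0.056 and 0.19. TNFSF10, the death ligand TRAIL, rose by 1.77 (SE 0.26, adjusted p = 0.0245, 1183 ± 248 against 346 ± 129). RAMP2, a partner of the adrenomedullin receptor in endothelium, was 2.36-fold higher in KNP (log2 1.24, SE 0.17, adjusted p = 0.0190). In the other direction CDKN2C, an inhibitor of the cell cycle kinases CDK4 and CDK6, lay at 53.1 ± 31.3 in KNP and 223 ± 54.1 in YS (log2 −1.89, SE 0.38, adjusted p = 0.0444). ALDH1A1, which oxidizes retinaldehyde to retinoic acid, lay at 34378 ± 2468 in KNP and 63122 ± 1818 in YS (log2 −0.88, SE 0.10, adjusted p = 0.00940). Its difference shrank to −0.30 after quantile normalization (adjusted p = 0.211). The YS values of SDS and the KNP values of CDKN2C lay near or below the array medians, so their size depends on the pseudocount: with 1 and 64 in place of 16, SDS showed 4.57 and 3.40, and CDKN2C −2.25, where its call was lost (adjusted p = 0.0638), and −1.31. Of the 12 genes with the largest rise and the 12 with the largest fall, only ATP2A2 and ALDH1A1 kept their call with each animal left out in turn. All of these genes were chosen without overlap between the breeds, so leaving out 1 animal could not change their direction.

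In all, 61 probe sets were higher and 88 lower in KNP, out of 14399. Leaving out 1 YS animal cut these 149 calls to 13, 23, 8 or 12 and leaving out 1 KNP animal to 53, 107, 78 or 119. With the actin ratio as a covariate, chosen after seeing the data, 0 of the 149 were called. This ratio did not overlap between the breeds, so that fit could hardly separate it from breed, and the lost calls do not show a cause. The brightest probe set of a gene was among the 149 for 27 genes higher and 47 lower. Counting any probe set, 37 genes had one called higher and 51 one called lower, and 54 of the 149 probe sets had no single symbol. All 4 KNP values lay on one side of all 4 YS values in 73 of the 74 genes called by their brightest probe set. The exception, GALP, was named after its values were seen; it lay at 146 ± 180 in KNP and 2210 ± 1413 in YS (log2 −3.96, SE 0.76, adjusted p = 0.0405). The KNP values of GALP lay below the array medians in 3 of 4 animals, so its size depends on the pseudocount, with −4.26 for 1 and −3.39 for 64. Over all probe sets tested, 1394 (9.68%) showed no overlap, where chance gives 2.86%. Breed took up 24.6% of the total sum of squares (exact permutation p = 0.0286, the smallest that 35 splits allow), and splits that mix the breeds take up a part of it as well.

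DAO, which oxidizes D-amino acids, rose by 1.25 (SE 0.21, adjusted p = 0.0336; 3019 ± 702 against 1263 ± 303). LRG1, a secreted glycoprotein induced in inflammation, rose by 1.19 (SE 0.23; 5231 ± 718 against 2370 ± 753), and ZFP36, which destabilizes cytokine messages, by 1.15 (SE 0.24; 1194 ± 328 against 515 ± 86.3), with adjusted p of 0.0401 and 0.0484. PLBD1, a phospholipase B-like protein, rose by 1.63, ASB3 by 1.43, DPF2 by 1.21, AKAP11, an anchor of protein kinase A, by 1.19 (1.35 and 0.87 with a pseudocount of 1, where its call was lost, and 64), and TMEM222 by 1.14, with adjusted p between 0.0314 and 0.0454. Other probe sets of some of these genes did not move with the one given: ATP2A2 has 3 more, with differences of 0.062, −0.056 and 0.19 (mean of all probe sets of ATP2A2 0.48, adjusted p = 0.299), the second probe set of ASB3 showed −0.019, those of DPF2 −0.10 and 0.68, and 1 of the 2 others of PLBD1 0.047. After quantile normalization, which gives all arrays one distribution, 10 probe sets were higher and 4 lower. All 61 probe sets called higher on the deposited scale kept their sign there with an unadjusted p under 0.05, against 49 of the 88 called lower; SDS (4.09), DAO (1.22), PLBD1 (1.61) and LRG1 (1.19) kept their size with adjusted p between 0.0642 and 0.0754. With their brightest probe set ATP2A2, TNFSF10, RAMP2, HPD and BBX were among them, all higher; other probe sets of B2M and PLBD1 were higher and one of RPS28 lower (−1.04), and 6 of the 14 had no single symbol. BBX, B2M and RPS28 were named after their values were seen. The brightest probe set of B2M showed −0.56 on the deposited scale, the 7 further probe sets of BBX lay between −0.46 and 0.12, and the brightest of RPS28 showed −0.11 after quantile normalization.

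GSN, gelsolin, which severs actin filaments, fell by 1.07 (SE 0.17, adjusted p = 0.0295), and PDGFRL by 1.26 (SE 0.24, adjusted p = 0.0390). CYP3A39, a drug-oxidizing cytochrome, fell by 1.09 (SE 0.22, adjusted p = 0.0440; 32998 ± 10341 against 67208 ± 1898). GSTA1, a glutathione transferase, fell by 0.96, UGT2B31, a glucuronosyltransferase, by 0.90, AHSG, the plasma protein fetuin-A, by 0.86, OAZ1, which limits polyamine synthesis, by 0.82, MAPK6 by 0.81, LOC396685 by 0.79, and CAT, catalase, which breaks down hydrogen peroxide, by 0.75. Their adjusted p lay between 0.0190 and 0.0422. The falls of the bright transcripts shrank with quantile normalization, CYP3A39 to −0.55 (adjusted p = 0.309), UGT2B31 to −0.58, ALDH1A1 to −0.30, GSTA1 to −0.37, AHSG to −0.33, LOC396685 to −0.24, CAT to −0.21 and OAZ1 to −0.22. CDKN2C (−1.79), PDGFRL (−1.29), GSN (−0.92) and MAPK6 (−0.82) kept most of their size. None of these falls had an adjusted p under 0.05 there.

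**Figure D1:**
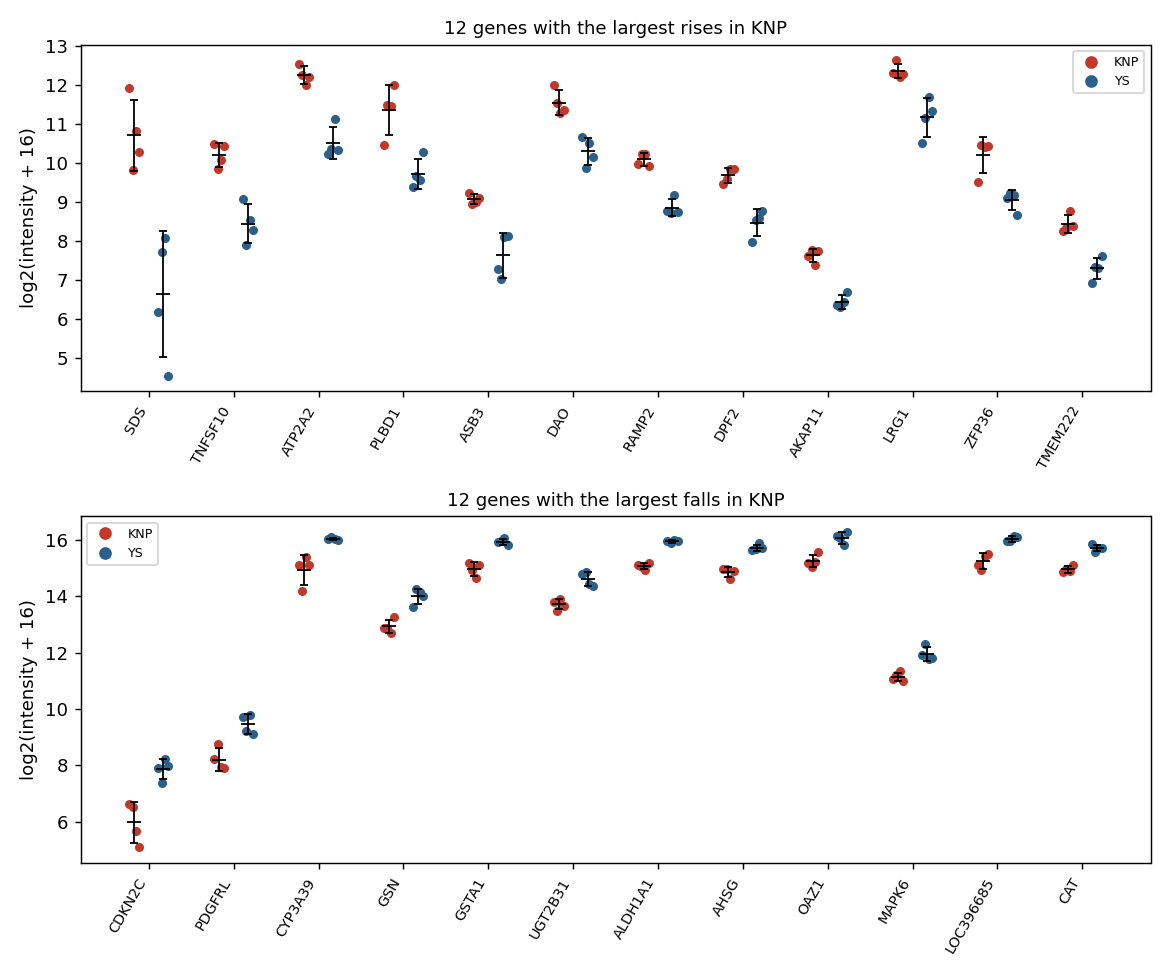
Log2 of intensity plus 16 (vertical axis) in each KNP and YS animal (points, n = 4 per breed), with the mean and 1 SD (bars), for the 12 genes with the largest rise (upper panel) and the 12 with the largest fall (lower panel) on the deposited scale. SDS shows the largest difference of the upper panel (log2 4.07) and CDKN2C that of the lower panel (log2 −1.89); CYP3A39, GSTA1, ALDH1A1, AHSG, OAZ1, LOC396685 and CAT are the brightest, with smaller differences after quantile normalization.

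Of 33 gene lists, camera called 2 higher and 10 lower in KNP. With an estimated correlation 0 lists were called by camera (5 at an unadjusted p under 0.05), while fry called 0 higher and 8 lower, 6 of them shared. Not called by fry were the cholesterol (adjusted p = 0.204), cell cycle (0.0741), fatty acid (0.437) and complement (0.104) lists. Nor did fry call the lists higher by camera, macrophage (adjusted p = 0.161) and immediate early (0.322). After quantile normalization camera called 4 lists higher and 3 lower, 5 of them shared with the values as deposited. With the actin ratio as a covariate, chosen after seeing the data, it called 2 higher and 8 lower, 7 of them shared. The hepatocyte, acute phase, complement, lipoprotein and immediate early lists lost their call there. This ratio did not overlap between the breeds, so these losses do not show a cause. Leaving out 1 animal ended the call of the complement list (KNP replicate 2 or YS replicate 4), the lipoprotein list (KNP replicate 3 or 4, or YS replicate 2), the cell cycle list (KNP replicate 4), the immediate early list (KNP replicate 2 or 4, or YS replicate 3 or 4) and the fatty acid list (KNP replicate 2, 3 or 4, or YS replicate 2).

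The list cholesterol synthesis and SREBP2 targets had the lowest median of the called lists, −0.93 over 11 tested members, which was −0.94 after quantile normalization and −0.85 after median centring, but −0.52 without KNP replicate 3 (adjusted p = 0.0116). The call had an adjusted p of 0.000783 (adjusted p = 0.451 with an estimated correlation). No single member passed over all genes, and 2 passed when adjusted over the list alone. HMGCS1, which makes the precursor of mevalonate, lay at 3723 ± 2184 in KNP and 11128 ± 5319 in YS (log2 −1.90, SE 0.67, adjusted p = 0.214), and MSMO1, a sterol methyl oxidase, at 17173 ± 8788 and 38414 ± 3591 (log2 −1.34, SE 0.34, adjusted p = 0.105). NSDHL and FDFT1, both sterol pathway enzymes, showed −0.54 and −0.98. KNP replicate 3 was the lowest array in HMGCS1 and FDFT1, at 490 and 1814, and without it they showed −1.08 and −0.53.

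The list fatty acid and triglyceride synthesis had a median of −0.30 over 21 members, of which none passed, also when adjusted over the list alone (adjusted p = 0.0490; adjusted p = 0.638 with an estimated correlation). The call was lost after quantile normalization (median −0.27, adjusted p = 0.0724), and the median was −0.13 without KNP replicate 3 (adjusted p = 0.258). SCD, which desaturates stearate, showed −2.04 (SE 0.73, adjusted p = 0.223; 8612 ± 8290 in KNP, 21992 ± 6108 in YS), FADS1, a desaturase of long fatty acids, −2.76 (adjusted p = 0.108), ME1, malic enzyme, −1.25 (adjusted p = 0.225) and ACSS2, which makes acetyl-CoA, −1.35 (adjusted p = 0.250). FASN, fatty acid synthase, showed −0.96 (SE 0.68, adjusted p = 0.544) with its brightest probe set and 0.55 and 0.40 with the others. ACACA, acetyl-CoA carboxylase, showed −0.18 (SE 0.33, adjusted p = 0.840). Without KNP replicate 3 the differences were −1.16 for SCD, −0.82 for ACSS2, −0.13 for FASN and 0.066 for ACACA.

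Of 17 conjugating and glutathione enzymes (phase II), 3 fell, 0 rose and 14 did not pass; adjusted over the list alone 7 fell and 1 rose. Their median was −0.42, with an adjusted p of 0.000356 (adjusted p = 0.163 with an estimated correlation), and −0.29 after quantile normalization. Besides GSTA1 and UGT2B31, the microsomal glutathione transferase MGST1 fell by 0.61, and EPHX1, which hydrolyses epoxides, showed −0.95 (adjusted p = 0.0643). SULT2A1, a sulfotransferase that conjugates steroids, showed −0.42 (SE 0.35, adjusted p = 0.607). Of 24 cytochrome P450 and phase I enzymes, ALDH1A1 and CYP3A39 fell, 0 rose and 22 did not pass; adjusted over the list alone 6 fell. The median was −0.46, with an adjusted p of 0.000783 (adjusted p = 0.163 with an estimated correlation), and −0.21 after quantile normalization, where the call was lost (adjusted p = 0.268). CYP1A1, which oxidizes aromatic hydrocarbons, lay at 648 ± 952 in KNP and 3194 ± 2951 in YS (adjusted p = 0.128). CYP2C33 showed −0.55 (adjusted p = 0.0926), and −0.03 after quantile normalization. The skatole-clearing cytochromes CYP2E1 and CYP2A19 showed −1.92 (SE 1.11, adjusted p = 0.452) and −3.35 (SE 1.18, adjusted p = 0.216), with KNP replicate 2 at 555 in CYP2E1 against 32831 to 39858 in the other KNP animals, and at 162 in CYP2A19 against 3421 to 24450. Without KNP replicate 2 the differences were −0.42 for CYP2E1, −1.87 for CYP2A19 and 0.016 for SULT2A1.

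**Figure D2:**
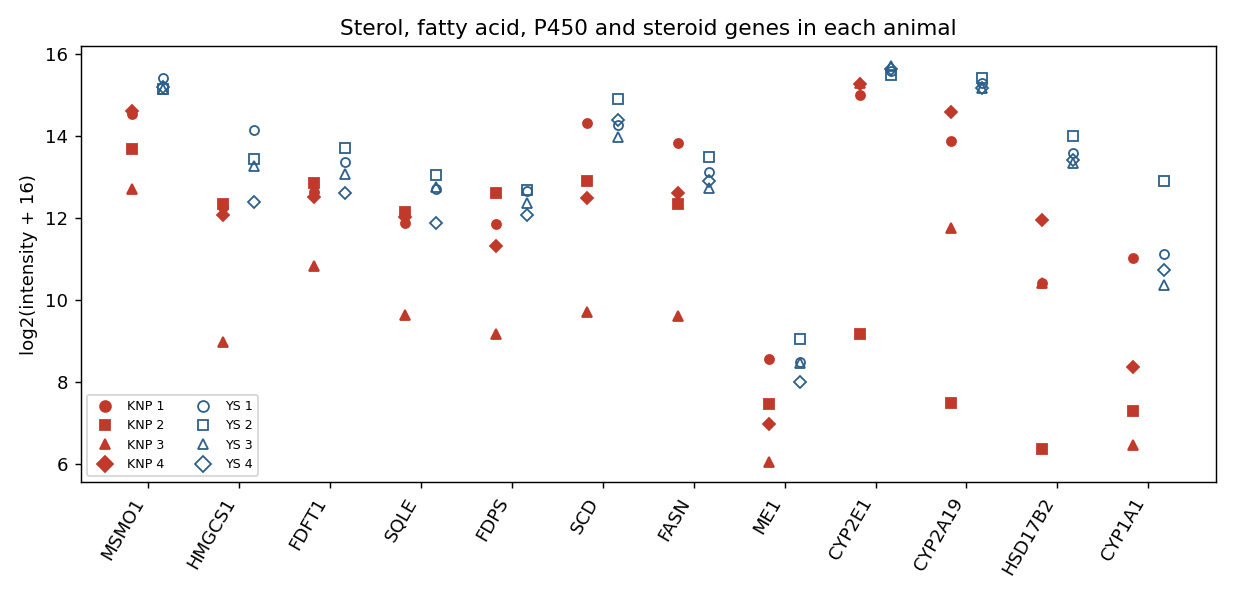
Log2 of intensity plus 16 (vertical axis) of 12 genes of sterol, fatty acid, cytochrome P450 and steroid metabolism in each animal, with a symbol per replicate number, KNP filled and YS open; SQLE and FDPS were chosen after their values were seen. KNP replicate 3 is the lowest array in HMGCS1 (490), FDFT1 (1814), SCD (821) and FASN (763), and KNP replicate 2 in CYP2E1 (555), CYP2A19 (162) and HSD17B2 (66.3).

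The hepatocyte, acute phase, complement, lipoprotein and ribosomal lists were called lower on the deposited scale and lost their call after quantile normalization; 2, 8, 8, 6 and 4 of their members had a higher mean in KNP. Among 12 hepatocyte markers 6 fell, 0 rose and 6 did not pass, 9 fell when adjusted over the list alone, and the median was −0.54 (0.016 after quantile normalization), with an adjusted p of 1.2e-06 (adjusted p = 0.163 with an estimated correlation). Among 25 acute phase genes 5 fell and 20 did not pass, 14 fell and 1 rose when adjusted over the list alone, and the median was −0.47 (0.037 after quantile normalization), with an adjusted p of 0.000235 (adjusted p = 0.451 with an estimated correlation). ALB, albumin, lay at 54702 ± 3867 in KNP and 88262 ± 5690 in YS (log2 −0.69, SE 0.10, adjusted p = 0.0245; −0.06 after quantile normalization). TF, the iron carrier transferrin, fell by 0.70, the haemoglobin binder HP by 0.66, fibrinogen beta FGB by 0.60 and the protease inhibitor SERPINA1 by 0.53, the last with 0.016 after quantile normalization.

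Of 28 complement and coagulation genes C3, the central complement protein, fell by 0.60 (0.0045 after quantile normalization) and 27 did not pass; adjusted over the list alone 7 fell and 1 rose. The median was −0.30 and turned to 0.069 after quantile normalization, with an adjusted p of 0.0196 (adjusted p = 0.491 with an estimated correlation). VTN, C1S and C8A showed −0.44, −0.45 and −0.95, and 0.17, −0.03 and −0.76 after quantile normalization. Of 17 lipoprotein and lipid transport genes 5 apolipoproteins fell and 12 members did not pass; adjusted over the list alone 6 fell and 1 rose. The median was −0.21 and turned to 0.017 after quantile normalization, with an adjusted p of 0.0338 (adjusted p = 0.301 with an estimated correlation). APOC3 fell by 0.69, APOA1 by 0.60, APOH by 0.56, APOB by 0.54 and APOE by 0.52, and the differences of APOA1, APOH and APOE turned to 0.017, 0.016 and 0.031 after quantile normalization.

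Of 55 cytosolic ribosomal proteins 11 fell, 0 rose and 44 did not pass, and 37 fell when adjusted over the list alone. The median was −0.37, with an adjusted p of 9.2e-17 (adjusted p = 0.301 with an estimated correlation), and −0.07 after quantile normalization, where the call was lost (adjusted p = 0.0973). With cyclic loess normalization, chosen after seeing the data, the call was kept. RPS26 fell by 0.69, RPL31 by 0.64, RPL5 by 0.62, RPL17 by 0.60, RPSA by 0.59 and RPS23 by 0.58, each with an SE of 0.11. Brightness moved with these falls. Probe sets with a mean log2 intensity of 13 to 14 had a median difference of −0.22, those of 14 to 15 of −0.39 and those of 15 to 17 of −0.58, against −0.06, −0.04 and −0.03 after quantile normalization. Of the 438 probe sets above 13, 63 were called lower, 0 of them also with limma after quantile normalization.

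The control signals of the arrays also differed. Spiked hybridization controls had a geometric mean of 3544 ± 615 on KNP arrays and 6050 ± 1099 on YS arrays (exact permutation p = 0.0286, n = 4 per breed). The ratio of the actin 3' to 5' control signals, which rises as RNA gets shorter, was 4.83 ± 1.88 in KNP and 10.5 ± 1.45 in YS (exact permutation p = 0.0286, n = 4 per breed). The GAPDH ratio was 3.04 ± 0.705 and 3.50 ± 0.407 (exact permutation p = 0.314, n = 4 per breed). The spiked controls and the actin ratio did not overlap between the breeds, so a hybridization batch, if there was one, and breed cannot be told apart.

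**Figure D3:**
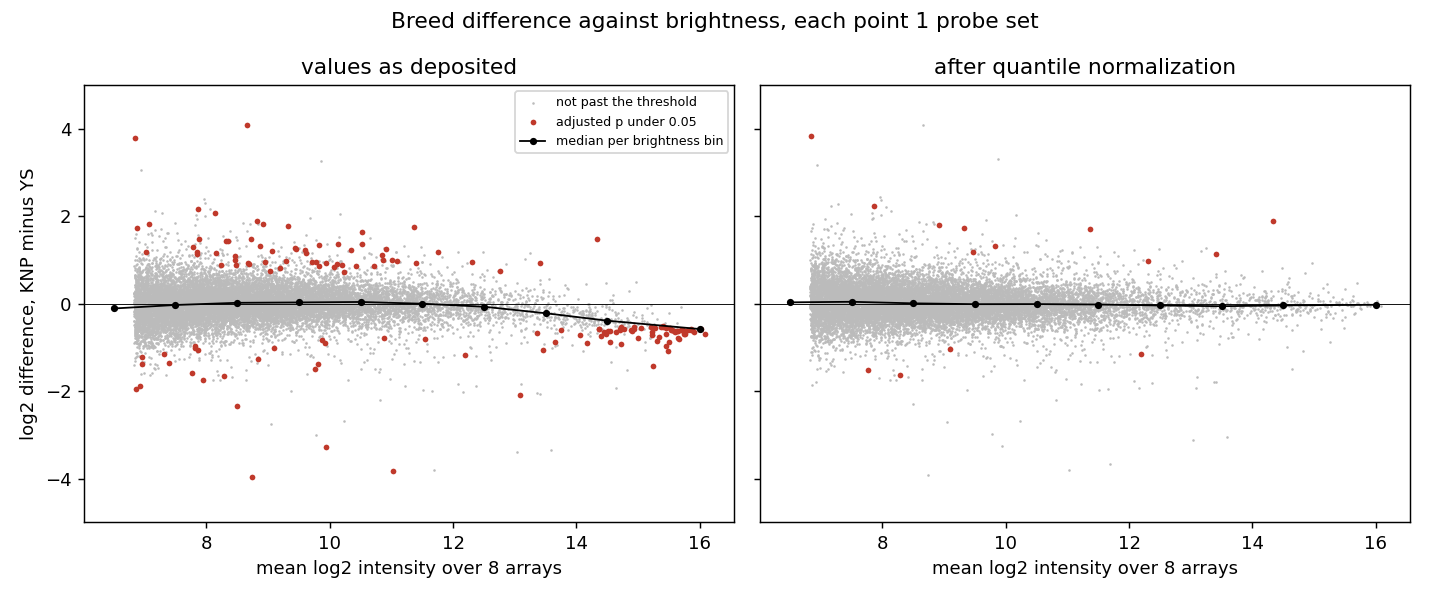
Log2 difference of KNP minus YS (vertical axis) of each tested probe set by its mean log2 intensity (horizontal axis), with the called probe sets coloured and the median per bin as lines, for the values as deposited and after quantile normalization. The median of the brightest bin lies at −0.58 on the deposited scale and at −0.03 after quantile normalization.

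The list Kupffer cell and macrophage markers was called higher in KNP, with a median of 0.44 over 10 members, 0.39 after quantile normalization and 0.51 after median centring, and of 0.22 without KNP replicate 3 or without YS replicate 1. The adjusted p was 0.0115 (adjusted p = 0.451 with an estimated correlation). FCER1G, a signalling chain of Fc receptors, rose by 0.93 (SE 0.17, adjusted p = 0.0384; 556 ± 80.0 against 283 ± 39.7), and 9 members did not pass; adjusted over the list alone 1 rose. TYROBP, its relative in myeloid cells, showed 0.65 (adjusted p = 0.217), and the complement subunits C1QC and C1QA, made by macrophages, 0.63 and 0.49, the latter 0.27 without YS replicate 1. Genes of the immediate early and glucocorticoid response had a mean of 0.28 and a median of 0.11 over 20 members, 14 of them higher in KNP, with an adjusted p of 0.0323 (adjusted p = 0.464 with an estimated correlation). ZFP36 rose, 19 did not pass, and 2 rose when adjusted over the list alone. After median centring the call was lost (adjusted p = 0.0645), and 5.58% of random lists of equally bright genes reached the median of the list on the deposited scale. FOS and EGR1, transcription factors induced within minutes of a stimulus, showed 1.29 (SE 0.32, adjusted p = 0.0923) and 0.91 (SE 0.33, adjusted p = 0.225), and NR3C1, the glucocorticoid receptor, 0.54 (adjusted p = 0.249).

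Cell cycle genes had a median of −0.37 over 13 members, none of which passed, also when adjusted over the list alone (adjusted p = 0.0194; adjusted p = 0.386 with an estimated correlation). The median was −0.32 after quantile normalization. TOP2A, which untangles DNA before division, lay at 186 ± 88.4 in KNP and 383 ± 72.7 in YS (log2 −1.08, SE 0.31, adjusted p = 0.130). CCNB1, cyclin B1, showed −1.48 (adjusted p = 0.282, and −0.78 without KNP replicate 3), and RRM1 and RRM2, subunits of ribonucleotide reductase, −0.54 and −0.64. The KNP values of CCNB1 (127, 218, 5.11 and 73.0) lay mostly below the array medians, so its size depends on the pseudocount.

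The urea cycle and amino acid list held SDS and HPD, which breaks down tyrosine and rose by 0.93 (SE 0.14, adjusted p = 0.0274; 15119 ± 2280 against 7911 ± 750). Of its 22 members 2 rose, also when adjusted over the list alone, 0 fell and 20 did not pass. Its median was 0.15 (adjusted p = 0.131), and after quantile normalization 0.25, where camera called it (adjusted p = 0.0173; adjusted p = 0.748 with an estimated correlation). T and NK cell markers had a median of 0.37 over 12 members (adjusted p = 0.0577) and were called after quantile normalization (median 0.44, adjusted p = 0.0462; adjusted p = 0.748 with an estimated correlation). CD247, the T cell receptor zeta chain, showed 1.44 (SE 0.42, adjusted p = 0.133) and GNLY, a granule protein of killer cells, 0.94 (adjusted p = 0.265).

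**Figure D4:**
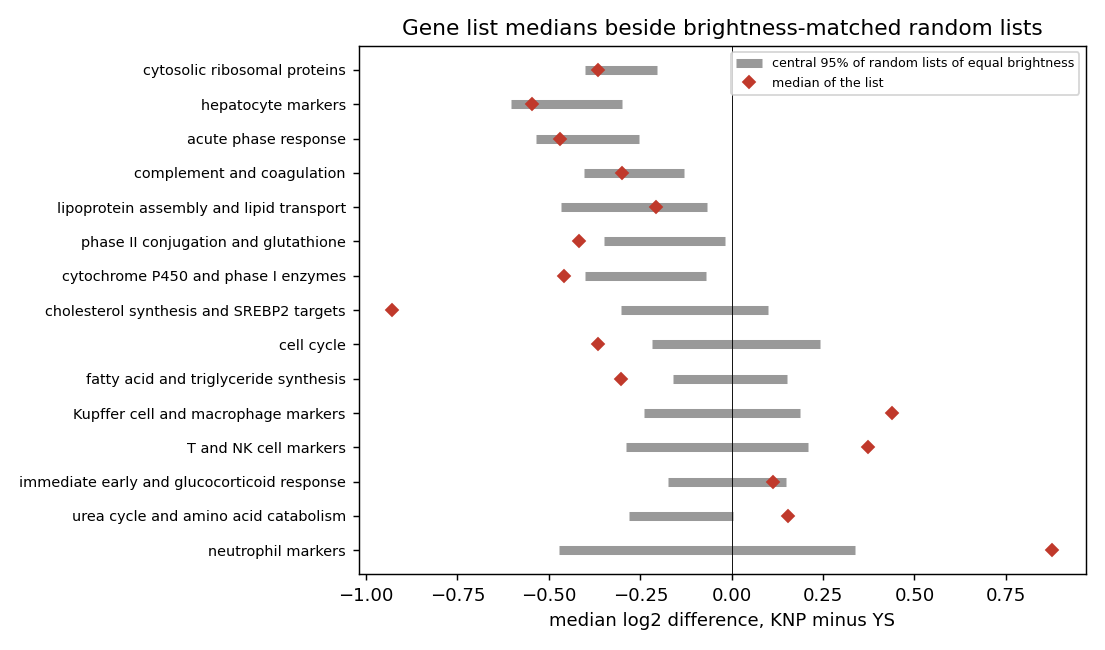
Median log2 difference of KNP minus YS (horizontal axis) of 15 gene lists (points) beside the central 95% of 10000 random lists of equally bright genes (bars), on the deposited scale. The medians of cholesterol synthesis (−0.93) and of Kupffer cell markers (0.44) lie outside the bars. Those of the ribosomal, hepatocyte, acute phase, complement, lipoprotein and immediate early (0.11) lists lie inside. After quantile normalization the medians of the hepatocyte, acute phase, complement and lipoprotein lists turn above 0.

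The list of the growth hormone and IGF axis did not pass. IGF1, the growth hormone effector made in liver, showed 0.59 (SE 0.29, adjusted p = 0.357; other probe sets 0.13 and −0.38), JAK2 0.71 (adjusted p = 0.167; other probe set −0.31) and GHR, the growth hormone receptor, −0.40 (SE 0.30, adjusted p = 0.564). Leaving out 1 animal took IGF1 to 0.35 (KNP replicate 3), GHR to −0.14 (KNP replicate 4) and IGFBP1 to 0.17 (YS replicate 4). IGF2 showed 0.53 (SE 0.18, adjusted p = 0.184) with its brightest probe set, while 4 of its 7 tested probe sets rose, by 0.99, 1.00, 1.12 and 1.37 (adjusted p between 0.0314 and 0.0479). The binding proteins IGFBP1 and IGFBP2 showed 0.75 (SE 0.62, adjusted p = 0.597) and −0.0026 (SE 0.37, adjusted p = 0.998), the latter turning to 0.073 after median centring. The list had an adjusted p of 0.814; its test and mean (0.06) pointed higher and its median (−0.0026) lower.

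None of the other lists passed. Their medians were 0.88 for neutrophil markers (adjusted p = 0.138), 0.22 for MHC and antigen presentation (0.131), 0.16 for sinusoidal and other endothelial markers (0.131), 0.37 for cholangiocyte markers (0.284), 0.23 for the circadian clock (0.284) and 0.02 for the unfolded protein response (0.839). Lower medians were −0.43 for steroid hormone metabolism (adjusted p = 0.0701), −0.14 for glycolysis and gluconeogenesis (0.131), where GAPDH fell by 0.72 with its brightest probe set (others −0.59, 0.27 and −0.36), −0.19 for the interferon response (0.229), −0.26 for bile acid synthesis (0.330) and −0.12 for heat shock proteins (0.792). After quantile normalization these medians were, in the same order, −0.18, −0.11, −0.22, −0.03 and −0.002. Retinoid metabolism had an adjusted p of 0.0632, with ALDH1A1 (log2 −0.88) and RBP4, the plasma retinol carrier (log2 −0.66, other probe set 0.28), past the threshold, and its median of −0.23 turned to 0.010 after quantile normalization. Iron and haem metabolism had an adjusted p of 0.170, and 4 of its members fell, among them TF and the ferritin chain FTL (log2 −0.64, other probe set 0.67); fry called both these lists lower. The adjusted p was 0.485 for the proteasome, where PSMB5 rose by 0.85, 0.672 for mitochondrial oxidative phosphorylation, 0.793 for stellate cell and fibroblast markers, 0.819 for fatty acid oxidation and 0.966 for erythroid markers. The medians of the iron, proteasome, mitochondrial, stellate cell and fatty acid oxidation lists changed sign after quantile normalization or median centring. For fatty acid oxidation the test and the mean (0.01) pointed higher and the median (−0.07) lower, and for erythroid markers the test and the median (0.07) higher and the mean (−0.12) lower. Fewer than 5 members were tested for Y-linked genes (1), B and plasma cell (4), adipocyte (3), skeletal and smooth muscle (4), gallbladder, pancreas and gut (2) and kidney and adrenal markers (1), and these lists were not tested.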

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

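The tests of brightness, of a signal ceiling, of RNA length, of hepatocyte share, of blood and of sequence variants were chosen only after the result was seen; the counts over splits of the arrays were planned.

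Of 272 groups of 4 animals examined, 17 (6.25%) held a value far from the other 3, where chance gives about 1 in 20 (5.04% of 100000 simulated groups of normal values). Both SQLE and CYP2C36 are among the 17 and were named after their values were seen; without the 6 genes named in this way, 15 of 260 groups (5.77%) held one. In KNP replicate 3, HMGCS1 lay at 490 (others 4317 to 5152), FDFT1 at 1814 (5815 to 7362), SQLE at 774 (3753 to 4530), CYP7A1, the first enzyme of bile acid synthesis, at 82.5 (2752 to 2987) and RPL17 at 19648 (22205 to 22595). The mean log2 intensity of the cholesterol synthesis genes was 10.76 in this animal and 12.19 to 12.36 in the other KNP animals. In KNP replicate 2, CYP2E1 lay at 555 (32831 to 39858), CYP2C36 at 24858 (53.4 to 94.5), MGST1 at 20354 (25652 to 26323) and PSMB5 at 2743 (2096 to 2130). ZFP36 lay at 704 in KNP replicate 1 (1329 to 1385) and VTN at 51399 in KNP replicate 4 (40481 to 42129). In YS replicate 3, ATP2A2 lay at 2213 (1181 to 1289) and RAMP2 at 562 (404 to 414). FADS1 lay at 3317 (956 to 1137) and TOP2A at 492 (340 to 357) in YS replicate 2, and CCNB1 at 155 (256 to 272) in YS replicate 4.

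Of the 10 lists called lower in KNP (0 with an estimated correlation), the ribosomal, hepatocyte, acute phase, complement and lipoprotein lists had a median that at least 8.41% of random lists of equally bright genes reached. A shift tied to brightness may therefore account for them. Among these 5 lists only the ribosomal list kept its call after cyclic loess normalization, chosen after seeing the data. The random lists left out only a list's own members. Genes of similar function could fill them, so brightness was not separated from function. Probe sets above a mean log2 intensity of 13 had a median of −0.33 where in no list and of −0.37 where in a list. At most 0.55% of random lists reached the median of the other 5 lists called lower, but random lists ignore the correlation within a pathway. With the animals as the unit, the gap to equally bright genes was −0.75 (SE 0.39, exact permutation p = 0.0286, the smallest possible, 1 of 10 lists so tested) for the cholesterol list. This argues against a shift tied to brightness as its whole cause. KNP replicate 3 lay at 10.76 in the mean of this list, against 12.19 to 12.36 in the other KNP animals, and the gap was not tested without it. The gap was −0.22 (SE 0.10, exact permutation p = 0.114) for phase II, −0.39 (SE 0.12, exact permutation p = 0.0571) for P450, −0.41 (SE 0.17, exact permutation p = 0.0857) for cell cycle and −0.63 (SE 0.39, exact permutation p = 0.171) for fatty acid genes, which leaves such a shift open there. A lower signal ceiling on KNP arrays was predicted to lower bright spiked controls more than dim ones. The 11 bright controls differed between the breeds by −0.76 and the 15 dim ones by −0.85, a gap of 0.088 (SE 0.035, exact permutation p = 0.0571). For pig probe sets of the same brightness the gap was −0.42 (SE 0.04), a difference of 0.51 (SE 0.05, exact permutation p = 0.0286). The shift with brightness was thus not seen in the spiked controls. A ceiling met before the scaling per array could shift bright and dim controls alike, so this test cannot exclude one. RNA length stays open: the gap between bright and other pig probe sets was −0.35, and −0.39 with the actin ratio as a covariate, but this ratio ran from 2.68 to 6.45 in KNP and from 8.39 to 11.8 in YS, without overlap, and cannot be told apart from breed. A hybridization batch that followed breed, for which the spiked controls (2747 to 4230 in KNP, 5167 to 7651 in YS) leave room, and a difference of breed or age in abundant liver transcripts are open too and could not be tested apart.

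Macrophage markers were called higher in KNP, and T and NK cell markers after quantile normalization, neither with an estimated correlation (adjusted p = 0.451 and 0.748). A lower share of hepatocytes could raise markers of all other cell types alike: macrophage markers per array differed by 0.39 (exact permutation p = 0.171) and stellate cell markers by −0.10 (exact permutation p = 0.800), and the gap between them by 0.49 (SE 0.37, exact permutation p = 0.229), too wide a spread to exclude it. More blood in the KNP samples could raise T and NK cell and erythroid markers together: these differed by 0.38 (exact permutation p = 0.0857) and −0.12 (exact permutation p = 0.743), and their gap by 0.50 (SE 0.32, exact permutation p = 0.143), which leaves this open as well. The differences per array for the other types were −0.58 for hepatocytes (exact permutation p = 0.0286), 0.22 for endothelium, 0.10 for cholangiocytes and 0.65 for neutrophils (exact permutation p = 0.171, 0.457 and 0.0857). After quantile normalization the hepatocyte difference was −0.13 (SE 0.17). On the deposited scale the gap of hepatocyte markers to equally bright genes was −0.14 (SE 0.15, exact permutation p = 0.486). Of the macrophage markers C1QA, C1QC and CTSS also stand in other lists, and a difference in immune cells between the breeds or ages is open and untested.

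Some calls rest on 1 of several probe sets, among them those of ATP2A2, ASB3, BBX and DPF2. Sequence variants between the breeds under 1 probe set may give such a call without a change of the transcript, as may splicing or a different end of the transcript. Among the 30 called genes with a mean log2 intensity of 13 or below, dim ones included, 10 had several tested probe sets. In 4 of the 10, 40% (95% Clopper-Pearson interval 12.2% to 73.8%), the others carried at least 0.5 of the change. The interval spans 50%, so the test decides neither way, and the array's probe sequences were not used here.

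The 149 probe sets called between the breeds were more than in any other of the 35 splits of the arrays, of which the highest gave 2 (1 of 35 splits with as many). This is the smallest share that 35 splits allow, so it argues against chance for this number without excluding it. After quantile normalization the 14 called were again reached in 1 of 35 splits, with 1 as the highest of the others. That count comes from the same arrays and is not separate evidence. For the number of gene lists chance stays open: 6 of the 35 splits, the real one included, gave at least the 12 lists of the breeds, and the highest other gave 17.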

How the results depend on the processing

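Cyclic loess normalization and the actin ratio as a covariate were chosen after seeing the data, and the other alternatives were planned. The actin ratio did not overlap between the breeds, so changes with this covariate cannot be told apart from breed. Over all single results and alternatives, 1926 kept direction and side of the threshold, 647 kept direction and lost the call, 26 gained one and 33 changed sign. None of the 24 genes with the largest changes reversed. Their choice without overlap between the breeds fixed this in advance for the fits that left out 1 animal. ATP2A2 kept its call in 17 of 20 alternatives but fell to 0.48 (adjusted p = 0.299) with the mean of all its probe sets. TNFSF10 kept its call in 16, RAMP2 in 15, ALDH1A1 in 14, SDS in 9 of 20 and CDKN2C in 3 of 19. Leaving out 1 animal, ATP2A2 and ALDH1A1 kept theirs each time, while RAMP2 lost it without YS replicate 1 (adjusted p = 0.0757), 2 (0.0536) or 4 (0.0762) and TNFSF10 without YS replicate 3 (0.0703) or 4 (0.0853). The share of variance between the breeds ran from 21.6% to 28.2% (variance explained by breed), with an exact permutation p of 0.0286 each time. The number of arrays, and signal over background for dim probe sets, limit what can be called.

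Against 61 probe sets higher and 88 lower, quantile normalization gave 10 and 4 (all 14 shared), cyclic loess 10 and 4 (14 shared), median centring 57 and 38, no filter 24 and 11, no intensity trend 8 and 5, the replicate block 6 and 2 (6 shared), at least 2-fold 36 and 24, a threshold of 0.01 2 (1 of B2M, named after its values were seen) and 3 (1 of ALDH1A1), and the actin covariate 6 and 2 (0 shared). The stricter thresholds count fewer by construction. Calls with the mean of all probe sets of a gene were 12 genes higher and 20 lower, against 27 and 47. Leaving out 1 animal gave 5 to 48 higher and 3 to 81 lower, in sum 53, 107, 78 and 119 without KNP replicate 1, 2, 3 and 4, and 13, 23, 8 and 12 without YS replicate 1, 2, 3 and 4. Fewer arrays lower the power, and why the YS animals weigh more was not tested. The spread within the breeds was unequal: the array weights, lower for arrays further from their breed, were 1.24, 0.70, 0.76 and 0.76 for KNP replicates 1 to 4. The YS arrays had weights from 1.06 to 1.32. Replicate numbers do not pair the animals: the correlation of same-numbered animals, across probe sets after removing breed means, was −0.02, 0.01, −0.01 and 0.05, within the range of other pairs. Pseudocounts of 1 and 64, the lower 60% left out and array weights gave 140, 157, 163 and 180 calls.

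Against 2 lists higher and 10 lower, quantile normalization gave 4 and 3, cyclic loess 4 and 4 (6 shared, the ribosomal list among them), median centring 1 and 10, the actin covariate 2 and 8 (7 shared), an estimated correlation 0 and 0, fry 0 higher and 8 lower (6 shared), and leaving out 1 animal 1 to 5 higher and 8 to 12 lower. With the actin covariate the list hepatocyte markers (adjusted p = 0.0515), the list acute phase response (0.684), the list complement and coagulation (0.969), the list lipoprotein assembly and lipid transport (0.0571) and the list immediate early and glucocorticoid response (0.235) lost their call, and the stellate cell, oxidative phosphorylation and ER chaperone lists gained one. Leaving out 1 animal at a time, 7 lists kept their call each time: cholesterol, P450, phase II, acute phase, ribosomal, hepatocyte and macrophage. The list complement and coagulation lost it without KNP replicate 2 (adjusted p = 0.111) and YS replicate 4 (0.0569), the list lipoprotein assembly and lipid transport without KNP replicate 3 (0.0635) or 4 (0.0605) and YS replicate 2 (0.0885), the list cell cycle without KNP replicate 4 (0.0702), and the list immediate early and glucocorticoid response without KNP replicate 2 (0.0648) or 4 (0.211, median 0.0021) and YS replicate 3 (0.0608) or 4 (0.129). Highest over all alternatives were 0.969, 0.794, 0.386 and 0.464 for these lists. Without KNP replicate 3 the list cholesterol synthesis and SREBP2 targets had a median of −0.52 (adjusted p = 0.0116; highest over its alternatives 0.451), and the list fatty acid and triglyceride synthesis −0.13 (adjusted p = 0.258; highest 0.638) and no call, which was also lost without KNP replicate 2 (0.146) or 4 (0.121) and YS replicate 2 (0.276).

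Signs changed as follows, and the cause was not tested. Quantile normalization gave SCP2 0.19, APOH 0.016, APOA1 0.017, APOE 0.031, SERPINA1 0.016, C3 0.0045, VTN 0.17, the list lipoprotein assembly and lipid transport 0.017, the list acute phase response 0.037 and the list complement and coagulation 0.069. Median centring gave IGFBP2 0.073, array weights 0.076 and cyclic loess 0.016; cyclic loess gave SCP2 0.12 and turned the test of the list complement and coagulation, with a median of −0.025. The actin covariate gave IGF2 −0.077, CRYAB −0.44, ARNTL 0.31, DBP −0.27, IGFBP1 −0.20, CYP2E1 2.53, SULT2A1 0.90, CYP2A19 0.43 and CYP2C36 −3.74. The mean of all probe sets gave FTL 0.013 and BBX −0.046. Leaving out 1 animal gave ACACA −0.39 to 0.066 (above 0 without KNP replicate 3), IGFBP2 −0.25 to 0.32, SULT2A1 −0.61 to 0.016 (above 0 without KNP replicate 2) and CYP2C36 −0.23 to 2.60 (below 0 without KNP replicate 2).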

Other observations

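The genes described here were singled out after their values were seen, and no further test was run on them. HSD17B2, which oxidizes testosterone and estradiol, lay at 1676 ± 1628 in KNP and 12464 ± 2754 in YS (SD, n = 4 per breed), without overlap; its brighter probe set showed −3.80 (SE 0.90, adjusted p = 0.0786) and the dimmer one fell by 3.28 (SE 0.59, adjusted p = 0.0362). Of 9 probe sets of B2M, the light chain of MHC class I, 1 rose by 1.49 (SE 0.16, adjusted p = 0.00857; 1.88 after quantile normalization), and the brightest showed −0.56 (SE 0.16, adjusted p = 0.130; −0.06 after quantile normalization). The neutrophil antimicrobial peptide genes NPG4 and PR39 showed 1.83 (SE 0.48, adjusted p = 0.106) and 1.56 (SE 0.55, adjusted p = 0.219), and SLA-DRB1, an MHC class II chain, 0.67 (adjusted p = 0.100).

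In KNP replicate 3 the fatty acid genes SCD and FASN lay at 821 and 763, and FDPS of the sterol pathway at 556, each the lowest of the 8 arrays. In KNP replicate 2 CYP2A19 lay at 162 and HSD17B2 at 66.3, also the lowest of the 8, and CYP2C36 at 24858, where the other 7 arrays lay between 36.1 and 149. Without KNP replicate 2 the difference of CYP2C36 went from 1.84 (SE 1.56, adjusted p = 0.614) to −0.23. The clock gene DBP showed 0.86 (SE 0.35, adjusted p = 0.276) and its regulator ARNTL −1.31 (SE 0.53, adjusted p = 0.275), and the heat shock proteins HSPB1 and CRYAB 0.95 (adjusted p = 0.0778) and 0.82 (adjusted p = 0.333). DBP lay at 2096 in KNP replicate 1 and at 547 to 1241 in the other KNP animals. CRYAB lay at 6398 in KNP replicate 2 and at 1691 to 2323 in the other KNP animals. The interferon-induced genes MX2 and IFI44L showed −0.66 (adjusted p = 0.170) and −0.49 (adjusted p = 0.360). The spiked poly-A controls (39 probe sets) differed by 0.41 (exact permutation p = 0.257), and the EF1A 3' to 5' ratio was 1.23 ± 0.226 in KNP and 1.63 ± 0.246 in YS (exact permutation p = 0.0571, n = 4 per breed).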
